A study of Mus musculus with 6 samples.

How the data were processed

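The series holds polyadenylated RNA sequencing of mouse liver from animals carrying tumours grown from Hepa 1-6 cells, a mouse hepatoma line. The labels place 3 libraries in a wild-type group (WT) and 3 in an Akr1d1-knockout group (KO), and the libraries are named here by group and replicate. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these samples only. Libraries were made with a kit named in the labels' protocols as NEBNext Ultra RNA; whether strand was used in counting is not given in the sources used here.

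The deposited table holds 12792 rows, each with a gene symbol and 1 value for each of the 6 libraries. The deposited values are a linear ratio. No value lies above 7, no row sums to more than 7 over the 6 libraries, and 99 rows sum to 7 within 1e-09, so each value reads as the gene's expression in that library divided by its mean over 7 libraries, 1 of which is not analysed here. This reading comes from the values, as no label or header states the step. It removes each gene's abundance relative to other genes, while ratios between libraries of the same gene are kept. STAR 2.10, R 4.0.5 and the mm10 build are named, per the submitters' processing notes, without a role or order. The counter, the annotation and the scaling of libraries before the division are not given in the sources used here.

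Of the rows, 189 had no value in any library and were left out, and 12603 had values in all 6. A total of 110 names stood in 2 or more rows (222 rows), and 20 rows had a date in place of a name. Rows sharing a name were tested but left out of the gene lists and of the rule for named genes. Gene positions were taken by symbol from GENCODE M21, which uses the same build, and 12334 rows had a name found there. Genes that overlap or share reads with close relatives, such as members of the Cyp2c, Cyp4a and Serpina1 families, are uncertain to that extent.

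Total reads per library are unknown. Relative depth was estimated from 184 rows that hold a 0, where ratios between libraries can fall on ratios of small whole reads. At the best offset between libraries 26.7% to 69.9% of these ratios lay within 0.008 (log2) of a ratio of whole numbers up to 6, depending on the pair of libraries, against at most 6.67% as the median over the offsets tried. The estimates, which rest on these partial shares, were 0.972, 0.867 and 1.02 for WT replicates 1 to 3, and 1.04, 1.02 and 1.07 for KO replicates 1 to 3, a range of 1.24-fold. With these steps, 226 rows could be written as at most 8 whole reads per library, within 0.1 of a read, against a mean of 92.6 rows when the worth of a read was set wrongly in 5 draws. Such rows are taken to rest on few reads, and some of them are chance matches. No pair of libraries had identical columns.

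The test written before the data were examined assumed counts or abundance units: limma with a mean trend on log2(value + 1), for genes with a value of at least 1 in at least 3 libraries. On a ratio to the gene's own mean, a value of 1 is not an abundance, so that filter keeps or drops rows by how the libraries differ, and a pseudocount of 1 compresses every fold change. The test used instead was limma 3.58.1 (R 4.3.3) without a mean trend on log2(value + 0.1), for the 12578 rows with a value above 0 in at least 3 libraries, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. This setting was chosen after the unit was seen, and the test as first written is given as an alternative. Log2 changes are on the log2(value + 0.1) scale, which understates changes of low values. Folds are the mean of the KO libraries over the mean of the WT libraries. The fit had 4 residual degrees of freedom and 1.87 prior degrees of freedom.

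Before the data were examined, 59 gene lists were fixed. The 54 with at least 5 tested members, leaving out a list for the sex of the animal kept as a check, were tested with limma's camera at its preset correlation of 0.01, adjusted over the 54 lists. Camera with a correlation estimated from the data and fry were run beside it. A list's score in a library is the mean of its members' log2 values, centred over the 6 libraries. The rule for named genes, also fixed before, took Akr1d1, then up to 10 genes per direction past the threshold, filled up to 5 by smallest p where fewer passed, with the groups not overlapping and with predicted genes and Rik names left out. It then took the 4 members with the smallest p of each list past the camera threshold and of 7 lists chosen in advance. The rule's abundance floor could not be applied to ratios, and 1 gene that the rule took is not reported here.

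The fit was tested on simulated values for 12578 genes, 200 of them changed. At 1.5-fold, 29.9% of changed genes were recovered, at 2-fold 62.7%, and at 4-fold 81.8%. It made 121 calls, of which 5 were false. These values were continuous, without zeros or steps of whole reads, and varied independently between genes. The shares thus do not cover rows of few reads, such as those of the genes called in the real values. A simulated shift of 1 list was recovered with 0 of 53 other lists called, in values simulated without correlation between genes. In the real values, the 9 splits that mix the groups call 3 to 19 lists. Alternatives covered scaling, mean trend, pseudocount, filters, thresholds, a replicate block and each library left out. Alternatives for counts only (edgeR and DESeq2 scaling and tests, voom) do not apply to ratios and were not run. Step and exact permutation calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.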

Results

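Liver RNA was compared between 3 libraries labelled wild type (WT) and 3 labelled Akr1d1 knockout (KO), all from mice bearing tumours of the mouse hepatoma line Hepa 1-6. The comparison asks how loss of *Akr1d1*, the steroid 5-beta-reductase of bile acid synthesis and steroid clearance, changes gene expression in the tumour-bearing liver. Each value is a gene's expression in 1 library relative to its mean over 7 libraries, 1 of which is not analysed here. Relative depth differed by 1.24-fold between the deepest and the shallowest library, and the total number of reads is unknown.

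*Akr1d1* (chromosome 6, 37530173 to 37568815, plus strand, mm10) was not lower in the libraries labelled KO. Its values were 0.826, 0.697 and 0.881 in the libraries labelled WT, and 1.21, 1.21 and 1.35 in those labelled KO. The means were 0.801 ± 0.0944 and 1.26 ± 0.0787 (SD, n = 3 each), a 1.57-fold higher mean in the libraries labelled KO, with every KO library above every WT library. The log2 change was 0.60 (SE 0.11), with a limma adjusted p of 0.17. A two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The targeted gene thus goes against the labels, and all directions in the following are between the libraries as labelled. A gene-level value does not tell which part of the gene was targeted, and an allele that leaves a non-functional transcript would not be seen in it.

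Of 12578 genes tested, 2 rose in the libraries labelled KO and 0 fell. Both matched very few reads. *Tnni2*, a fast skeletal muscle troponin (chromosome 7, 142441808 to 142444410, plus strand), was listed at 0 in all 3 libraries labelled WT and had a mean of 2.33 ± 0.0634 (SD, n = 3) in those labelled KO, with a limma adjusted p of 1.45e-05. The smallest whole reads that give its values are 1 in each library labelled KO. *4930511A08Rik*, named after its values were seen because it is 1 of the 2 genes that passed, was listed at 0 in all 3 libraries labelled WT, with values that match 1, 1 and 2 reads in those labelled KO (adjusted p = 0.0145). With a mean trend in limma 0 genes passed, and the test as written before the data were examined called 16, of which 14 were higher and 2 lower. Without WT replicate 2, KO replicate 1, WT replicate 3 and KO replicate 2 the count was 1, 1, 4 and 4.

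Differences short of the threshold were many. At an unadjusted p under 0.05, 818 genes had higher and 696 lower values in the libraries labelled KO, 1514 in all, where chance alone gives 629. The groups did not overlap in 18.99% of genes, where chance gives 10%. At an adjusted p under 0.1 the count was 44, of which 30 were higher and 14 lower.

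Among the genes with the smallest p in each direction, none of the following passed the threshold. *Ly6d* (chromosome 15, 74762056 to 74763620, minus strand), a surface antigen of the Ly6 family, had a 4.43-fold higher mean in the libraries labelled KO (log2 change 1.89, SE 0.16, adjusted p = 0.0809). The scaffold gene *Sh3pxd2b* was at 2.34-fold, *Zfr2* at 2.05-fold and *Fhit* at 1.92-fold. On the lower side, *Wnk4* (chromosome 11, 101260567 to 101277409, plus strand), a kinase of ion transport, had a mean of 0.266 ± 0.0845 in the libraries labelled KO against 1.39 ± 0.289 (SD, n = 3 each), a ratio of 0.192 (log2 change -2.03, SE 0.22, adjusted p = 0.0842). The ratio was 0.289 for *Ier5l*, 0.429 for *Kcp*, 0.482 for the cell adhesion gene *Cadm4* and 0.570 for *Sall2*. Without KO replicate 2, *Ly6d* passed with an adjusted p of 0.0402. With the test as written before the data were examined, *Ly6d*, *Sh3pxd2b* and *Zfr2* each had an adjusted p of 0.0366, *Fhit* 0.0342 and *Sall2* 0.0397, while *Kcp* (0.0689), *Cadm4* (0.085), *Ier5l* (0.298) and *Wnk4* (0.326) did not pass.

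**Figure D1:**
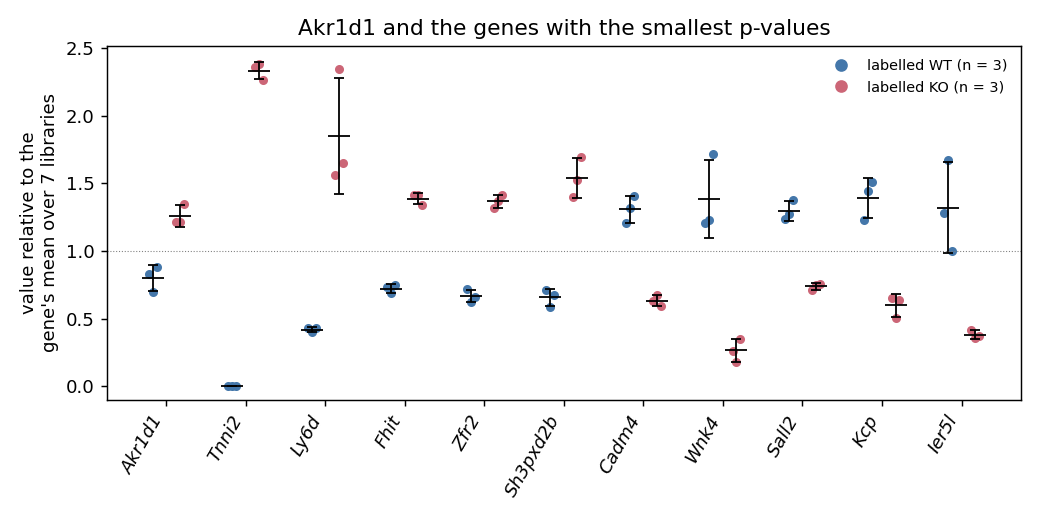
Values of *Akr1d1* and of the genes with the smallest p in each direction, relative to each gene's mean over 7 libraries. Points are libraries, horizontal marks the means and bars the SD (n = 3 per group); *Akr1d1* lies at 0.801 on average in the libraries labelled WT and 1.26 in those labelled KO.

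Gene lists fixed in advance gave more. Of 54 lists, 14 changed by camera at its preset correlation, 12 upward and 2 downward in the libraries labelled KO. In each of them 0 members passed the test over all genes. With an estimated correlation 0 of the 54 lists passed, the smallest adjusted p being 0.592, and fry called 2 lists, neither of them among the 14. List scores did not overlap between the groups for 7 of the 14, and overlapped for the ductular, type I interferon, interferon-gamma, male-biased, fatty acid synthesis, cell cycle and fetal lists.

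Sterol synthesis had the smallest camera p at the preset correlation, though not the largest median. The list of cholesterol synthesis genes and targets of SREBP2, the transcription factor that drives that pathway, rose (median log2 change 0.39, camera adjusted p = 1.9e-07; adjusted p = 0.613 with an estimated correlation). Of its 22 members, 20 had a positive log2 change and 11 passed when adjusted over the list alone. In 11 every KO library lay above every WT library, where chance gives 5% and 1114 of all 12578 genes did so. *Idi1* had a 1.86-fold higher mean, *Fdps* 1.66-fold and *Cyp51* 1.51-fold, all enzymes on the route from mevalonate to cholesterol.

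Lipid genes also rose as lists. For PPARA targets and fatty acid oxidation the median log2 change was 0.23 (26 of 32 members positive, 3 passing when adjusted over the list alone, camera adjusted p = 7.74e-06; adjusted p = 0.613 with an estimated correlation). The fatty acid transporter *Cd36* had a 3.09-fold higher mean (log2 change 1.45, SE 0.15, adjusted p = 0.0842) and the omega-hydroxylase *Cyp4a14* a 2.43-fold higher mean, while *Ehhadh* and *Acaa1b*, of peroxisomal beta-oxidation, stood at 1.47- and 1.40-fold. Without WT replicate 1 the PPARA median was 0.14. For fatty acid synthesis and LXR or SREBP1 targets the median was 0.36 (22 of 29 positive, 1 passing over the list alone, camera adjusted p = 0.0015; adjusted p = 0.613 with an estimated correlation). *Elovl5*, an elongase of polyunsaturated fatty acids, had a 1.89-fold higher mean, *Acss2* 1.71-fold and the desaturase *Scd1* 1.65-fold, while the triglyceride synthesis gene *Dgat2* had a ratio of 0.780. For this list WT replicate 1 scored 0.17, above KO replicates 1 and 3 (-0.003 and 0.13), and the median was 0.19, 0.15, 0.22 and 0.23 without WT replicate 2, WT replicate 3, KO replicate 2 and KO replicate 3. *Elovl5* had an adjusted p of 0.0877, and 0.0366 with the test as written before the data were examined.

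Bile acid genes, the pathway *Akr1d1* belongs to, moved in both directions. Their lists did not pass camera, which tests for a shift in 1 direction. The bile acid synthesis enzymes had a median log2 change of 0.01 (11 of 19 positive, camera adjusted p = 0.777), with 1 member higher and 1 lower when adjusted over the list alone. In 4 members every KO library lay above every WT library, and in 4 below. Fry's test for changes in either direction gave an unadjusted p of 2.59e-05 for this list and 0.00108 for the transporters. The same fry test gave smaller values for several lists that camera did not call either. Among them were 9.54e-07 for the unfolded protein and integrated stress response, 1.95e-06 for stellate cell markers and 2.74e-06 for urea cycle genes. Pericentral hepatocyte genes had 4.88e-06, so this test does not set the bile acid lists apart. *Cyp7a1*, the rate-limiting enzyme, had a mean of 1.68 ± 0.855 in the libraries labelled KO against 0.532 ± 0.0615 (SD, n = 3 each), 3.15-fold, with an adjusted p of 0.262. The 12-alpha-hydroxylase *Cyp8b1* had a 1.67-fold higher mean (adjusted p = 0.143) and the peroxisomal transporter *Abcd3* a 1.26-fold one, while the oxysterol hydroxylase *Cyp39a1* had a ratio of 0.380 (adjusted p = 0.134). Among bile acid transporters (median -0.06, camera adjusted p = 0.264), the sterol exporters *Abcg5* and *Abcg8* had ratios of 0.737 and 0.749, *Slco1a4* 0.684 and the phospholipid exporter *Abcb4* 1.28, and 2 members passed as lower when adjusted over the list alone. The transporter median was -0.10, -0.01 and -0.11 without WT replicate 2, WT replicate 3 and KO replicate 3.

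**Figure D2:**
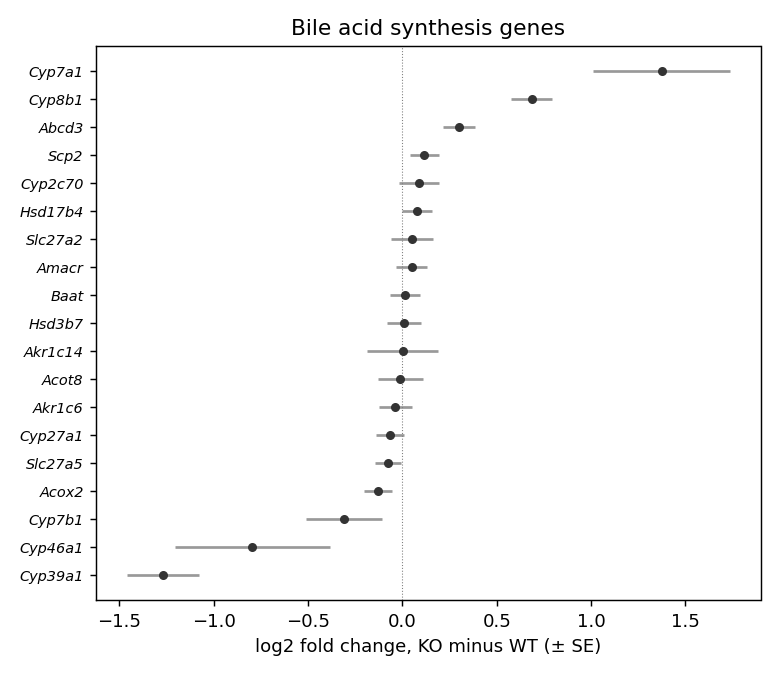
Log2 change of each tested member of the bile acid synthesis list, libraries labelled KO minus libraries labelled WT, on the log2(value + 0.1) scale. Points are estimates and bars standard errors (n = 3 per group); 11 of 19 members lie above 0 and the others below.

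Sex-biased liver genes moved apart. Female-biased genes rose (median log2 change 0.83, 11 of 12 members positive, 4 passing when adjusted over the list alone, camera adjusted p = 8.93e-05; adjusted p = 0.592 with an estimated correlation). *A1bg* had a mean of 2.20 ± 1.41 in the libraries labelled KO against 0.0647 ± 0.112 (SD, n = 3 each), with WT replicates 2 and 3 listed at 0. The P450 genes *Cyp2c40* and *Cyp2c69* had 3.66- and 3.57-fold higher means and *Atp6v0d2* 1.88-fold. WT replicate 1 scored -0.07 for this list against -0.71 and -0.66 in WT replicates 2 and 3, and the median was 0.49 without WT replicate 3. Male-biased genes fell (median -0.20, 15 of 17 negative, 0 passing when adjusted over the list alone, camera adjusted p = 0.00137; adjusted p = 0.613 with an estimated correlation), with *Hsd3b5* at a ratio of 0.604, *Serpina1e* at 0.728, *Selenbp2* at 0.749 and *C8a* at 0.855. WT replicate 1 scored -0.14 for the male-biased list, below KO replicates 1 and 2 (0.02 and -0.06), and the median was -0.12 without WT replicate 2. The Y-linked genes *Kdm5d*, *Eif2s3y*, *Uty* and *Ddx3y* had values above 0 in all 6 libraries, and the lowest among the libraries labelled KO was 0.822. In WT replicate 1 *Uty* was at 0.280 and *Ddx3y* at 0.472, with *Kdm5d* at 1.13 and *Eif2s3y* at 0.821.

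Complement and coagulation genes, mostly hepatocyte products, fell slightly (median -0.10, 28 of 34 negative, camera adjusted p = 0.0015, or 0.592 with an estimated correlation), with 0 members passing when adjusted over the list alone. In 14 members every KO library lay below every WT library, where chance gives 5% and 1275 of all 12578 genes did so. *F7* had a ratio of 0.804, *Cfb* 0.827 and *C1ra* 0.835, while *Cfd*, which adipocytes make, had a 3.43-fold higher mean. Its value was 2.77 in KO replicate 3, against 1.11 and 0.845 in KO replicates 1 and 2. KO replicate 3 also had the highest score for the adipose list (0.24), which did not pass camera (adjusted p = 0.777). Hepatocyte identity genes had a median of -0.07 and did not pass (camera adjusted p = 0.0867). Of their 34 members 25 were negative, 10 had every KO library below every WT library and 2 above. Their scores did not overlap between the groups.

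Matrix genes and some marker lists of other liver cells rose, while other marker lists did not pass. Extracellular matrix genes had a median log2 change of 0.25 (25 of 34 positive, 4 passing when adjusted over the list alone, camera adjusted p = 3.21e-05; adjusted p = 0.613 with an estimated correlation). The fibrillar collagens *Col1a1* and *Col3a1* had 1.75- and 1.55-fold higher means, *Postn* 1.70-fold and *Eln* 1.49-fold. Without KO replicate 2 the median was 0.14. *Col1a1* itself had an adjusted p of 0.0842, and 0.0366 with the test as written before the data were examined. Cholangiocyte and ductular markers had a median of 0.50 (15 of 17 positive, 2 passing over the list alone, camera adjusted p = 3.21e-05; adjusted p = 0.613 with an estimated correlation), with *Spp1* at 2.02-fold, *Anxa2* at 1.56-fold, *Bicc1* at 1.47-fold and *Anxa5* at 1.44-fold. KO replicate 3 scored -0.17 for the ductular list, below WT replicate 1 (-0.06) and above WT replicates 2 and 3. Monocyte and macrophage markers had a median of 0.28 (23 of 27 positive, 0 passing over the list alone, camera adjusted p = 0.000284; adjusted p = 0.592 with an estimated correlation), with *Ly6c2* at 2.18-fold, *Mpeg1* at 1.60-fold and *Adgre1* at 1.34-fold. *Spp1* is a member of both the ductular and the macrophage list. Endothelial markers (median -0.11, camera adjusted p = 0.241) and stellate cell markers (median 0.09, camera adjusted p = 0.191) did not pass. Kupffer cell markers, those of the liver's resident macrophages, had a median of 0.10 with overlapping scores and did not pass either (camera adjusted p = 0.0571).

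Interferon-response lists rose, and their calls were lost without 1 library. The type I list had a median log2 change of 0.26 (33 of 36 positive, 0 passing when adjusted over the list alone, camera adjusted p = 0.000153; adjusted p = 0.613 with an estimated correlation), with *Ifit2* at 1.72-fold, *Trim30a* at 1.58-fold, *Oasl2* at 1.49-fold and *Ifih1* at 1.37-fold. The interferon-gamma list had a median of 0.37 (24 of 26 positive, 2 passing over the list alone, camera adjusted p = 0.000284; adjusted p = 0.624 with an estimated correlation). *Ubd* had an 8.71-fold higher mean (log2 change 2.62, SE 0.30, adjusted p = 0.0877), *Gbp4* 2.40-fold, the chemokine *Cxcl9* 1.97-fold and *Cd274*, which encodes PD-L1, 1.92-fold (adjusted p = 0.098). The groups overlapped for *Gbp4* and *Cxcl9*, and the log2 change of *Cxcl9* was 0.87, or 0.58 without KO replicate 1. Without KO replicate 1 the adjusted p was 0.121 for the type I list and 0.216 for the interferon-gamma list, with medians of 0.11 and 0.10. Without WT replicate 2 the medians were 0.17 and 0.23, and without KO replicate 2 the interferon-gamma median was 0.56. With the test as written before the data were examined the adjusted p was 0.193 and 0.0909, with medians of 0.08 and 0.13.

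Lymphocyte lists lay around the threshold. Cytotoxic effector genes rose (median 0.51, 10 of 14 positive, 0 passing over the list alone, camera adjusted p = 0.0339; adjusted p = 0.613 with an estimated correlation), with *Xcl1* at 2.05-fold, *Klrk1* at 1.82-fold, *Tnfsf10* at 1.67-fold and *Srgn* at 1.26-fold. The groups overlapped for *Xcl1* and *Srgn*, and the log2 change of *Tnfsf10* was 0.70, or 0.42 without WT replicate 2. NK cell markers (median 0.22, 2 passing over the list alone) and T cell markers (median 0.31, 0 passing over the list alone) each had a camera adjusted p of 0.0554. *Xcl1*, *Klrk1* and *Tnfsf10* are members of the NK list too, so the cytotoxic and NK lists are not separate evidence. With an estimated correlation the camera adjusted p was 0.613 for NK cell markers and 0.592 for T cell markers. *Cxcr6* had a 1.89-fold higher mean, *Cd3d* 1.84-fold, *Zap70* 1.81-fold and *Cd2* 1.79-fold, against a ratio of 0.282 for *Cd27*. The cytotoxic list missed the threshold without WT replicate 1, WT replicate 2 or KO replicate 2 (adjusted p = 0.0563, 0.103 and 0.0976, with medians of 0.29, 0.34 and 0.46). It also missed it with the test as written before the data were examined (0.12) and with few-read rows left out (0.0908). The same held with only genes above 0 in every library and no pseudocount (0.0507). With the test as first written NK markers passed (0.0199). They also passed without WT replicate 3 or KO replicate 2 (0.00865 and 0.0205, with medians of 0.37 and 0.23), and T cell markers without WT replicate 2 or KO replicate 3 (0.0418 and 0.0419, with medians of 0.39 and 0.55). The NK median was 0.09 without KO replicate 1.

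Proliferation and fetal genes rose as lists. Cell cycle genes had a median log2 change of 0.19 (29 of 37 positive, 1 passing when adjusted over the list alone, camera adjusted p = 0.00778; adjusted p = 0.613 with an estimated correlation), with *Kif20a* at 1.87-fold, *Cdk1* at 1.65-fold and the replication licensing gene *Mcm2* at 1.46-fold, against a ratio of 0.634 for the cyclin *Ccne1*, whose log2 change was -0.56, or -0.35 without WT replicate 1. Values of *Cdk1* and *Xcl1* match few whole reads per library. Fetal liver and hepatoma markers had a median of 0.24 (21 of 30 positive, 2 passing over the list alone, camera adjusted p = 0.0235; adjusted p = 0.613 with an estimated correlation), with *S100a11* at 1.57-fold, *Vim* at 1.37-fold and *Mycn* at a ratio of 0.304. The cell cycle list missed the threshold without WT replicate 3 or KO replicate 1 (adjusted p = 0.203 and 0.054), with medians of 0.12 and 0.17, and its median was 0.33 and 0.12 without WT replicate 1 and KO replicate 2. The fetal list missed it without WT replicate 2, KO replicate 1 or KO replicate 2 (0.102, 0.116 and 0.0976), the median being 0.15 in the last case.

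**Figure D3:**
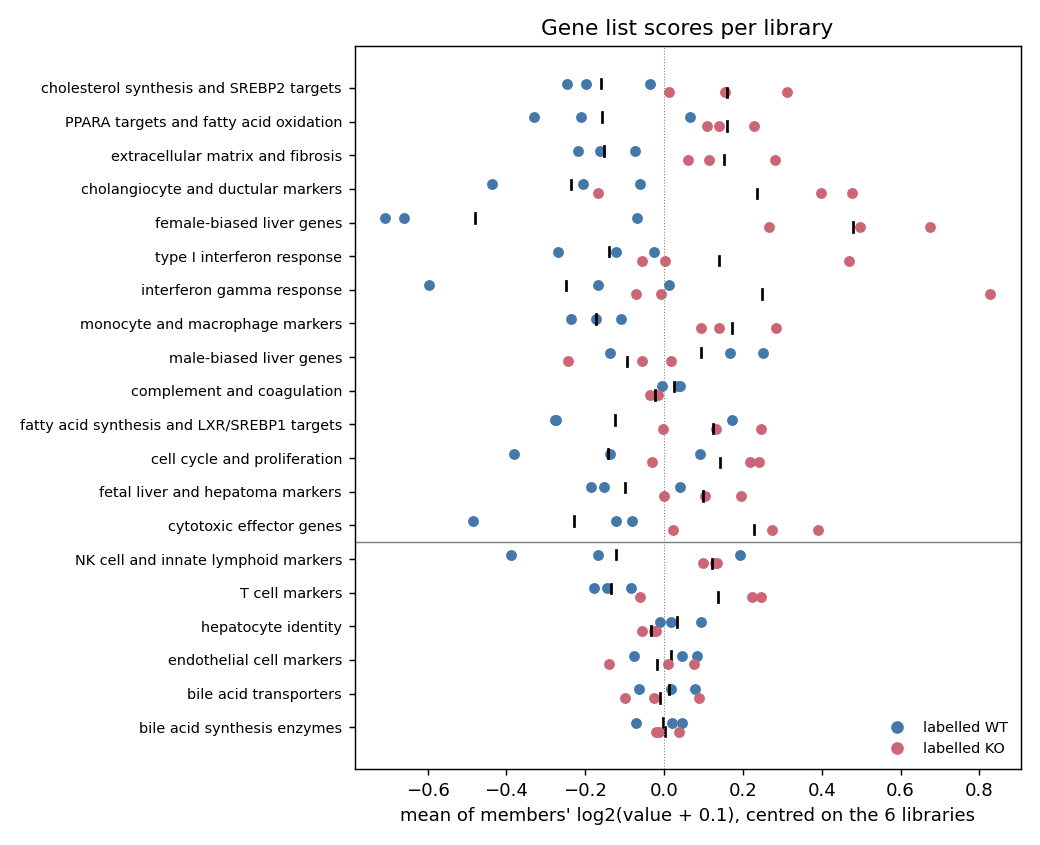
Score of each gene list per library, the mean of its members' log2(value + 0.1) centred over the 6 libraries, for the 14 lists past the camera threshold (above the line) and 6 others. Points are libraries (n = 3 per group) and vertical marks the group means; KO replicate 1 stands above the other libraries in both interferon lists.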

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

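The alternatives with pseudocount 0.01, no zeros, few-read rows left out, shared names left out and robust limma were chosen after seeing the data, as was the setting used. The count of 2 genes, both higher, became 0 with a mean trend, with genes above 0 in every library and no pseudocount, and with few-read rows left out; the last 2 settings remove both called genes, and the cause under the trend was not tested. It became 1 with pseudocount 1 and at an adjusted p under 0.01, 44 (30 higher, 14 lower) under 0.1, and 16 (14 higher, 2 lower) with the test as written before the data were examined, which tested 8664 genes; the cause was not tested. Leaving out 1 library gave 1 to 4, all higher. The replicate numbers were not taken to pair the libraries: deviations of same-numbered libraries correlated at -0.0324, -0.0135 and 0.0677, and only replicate 3 of each group correlated best with its own number. With the replicate block 1 gene passed, higher, and 13 lists, the cytotoxic list dropping out (adjusted p = 0.0544). The second principal component (20.2% of variance) set WT and KO replicates 3 (20.6 and 20.5) apart from the others (-12.1 to -7.24). *Akr1d1* kept its direction and stayed short of the threshold in all 18 alternatives run, with log2 changes of 0.33 to 0.66 and adjusted p of 0.085 to 0.392. The 14 lists became 0 with an estimated correlation, and fry called 2 lists, neither of them among the 14. Leaving out 1 library gave 11 to 19 lists. The bile acid synthesis list had medians of -0.0122 (without WT replicate 1) to 0.0549 (without WT replicate 2). A filter of 5 or more in 3 libraries leaves no gene, as rows sum to at most 7, and gave no value. Without abundance or total reads, low genes cannot be told from high ones except by read steps.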

Other observations

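Genes in this and the next paragraph were named after their values were seen, and none passed the threshold over all genes. *Asns*, asparagine synthetase and a target of the integrated stress response, had a 5.68-fold higher mean in the libraries labelled KO (log2 change 2.23, SE 0.28, adjusted p = 0.098). Other stress response and related genes lay on both sides, each with overlapping groups. The ratio was 0.708 for *Phgdh*, 0.779 for *Hspa5*, 0.836 for *Sesn2*, 0.877 for *Trib3*, 0.938 for *Ddit3*, 0.955 for *Shmt2* and 0.956 for *Chac1*. It was 1.504 for *Fgf21*, 1.37 for *Atf3*, 1.13 for *Dnajb9* and 1.11 for *Sdf2l1*. The list of unfolded protein and integrated stress response genes had a median of -0.05, a mean of 0.01 and a camera adjusted p of 0.287, with 12 of 28 members positive. *Osbpl3*, a lipid-binding protein gene, stood at 6.25-fold, *Mfsd2a* at 5.52-fold, the fasting-responsive kinase gene *Pdk4* at 3.44-fold and *Bhmt*, of methionine metabolism, at 1.77-fold. On the lower side *Cyp1a2* had a ratio of 0.619, *Ndrg1* 0.620 and *Apom* 0.664. *Nr0b2*, which encodes the repressor SHP that acts on *Cyp7a1*, had a ratio of 0.576 (adjusted p = 0.324). The list of bile acid receptors and their feedback genes, however, had a median of -0.07 and did not pass camera (adjusted p = 0.21). *Abcb11* had a ratio of 0.961, *Slc10a1* 0.952 and *Nr1h4* 1.07, each with overlapping groups.

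*Jchain*, a plasma cell gene, had a 7.32-fold higher mean in the libraries labelled KO (log2 change 2.40, SE 0.38, adjusted p = 0.143), while B and plasma cell markers did not pass as a list (median 0.28, camera adjusted p = 0.184). *Lyve1* stood at 1.87-fold against the endothelial list's median of -0.11. *Fam19a2* has 2 rows, with means of 2.20 and 2.05 in the libraries labelled KO against 0.0683 and 0.0704, each with 1 library labelled WT at 0. *Afp*, the fetal liver marker, has 2 rows at 1.72- and 1.45-fold. The 2 lists that fry called were circadian clock genes, downward (median -0.20), and p53 targets, upward (median 0.09), each with a fry adjusted p of 0.0224, and neither passed camera (0.0571 and 0.21). Neither list moved as a whole: 13 of 19 clock members were negative and 6 positive, and 14 of 22 p53 members were positive and 8 negative. The clock genes *Npas2* and *Arntl* had ratios of 1.38 and 1.30, against 0.672 for *Per3*, 0.780 for *Dbp* and 0.820 for *Nr1d1*. The groups overlapped for all of these but *Npas2*. The p53 target *Cdkn1a* stood at 1.67, *Ccng1* at 1.09 and *Mdm2* at 0.847.

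Of the tests that follow, all but that of the genes around *Akr1d1* were chosen after the result was seen. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. For genes changed, 2 splits gave at least the real 2, the highest other being 2, and likewise 2 splits for genes higher, with 2 as the highest other in either direction. For genes lower the real count was 0, which all 10 splits reach by construction, with 2 as the highest other in either direction. For gene lists, 2 splits gave at least the real 14, and the 9 others gave 3 to 19. The real split gave the largest score difference for 7 of the 14 called lists and for 7 of the 40 others. For the fatty acid synthesis, male-biased and interferon-gamma lists 3 of the 10 splits gave a difference as large, the real one included, and for the ductular, type I interferon, cell cycle and fetal lists 2 did. At an unadjusted p under 0.05 the real split gave 1514 genes and the others 314 to 759, and at an adjusted p under 0.1 it gave 44 and the others at most 2.

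*Akr1d1* was higher, not lower, in the libraries labelled KO. The lower group held 63.6% (SE 4.90) of the other group's mean. This cannot decide on an exchange of the group labels with an allele that removes the transcript, because RNA from the tumour cells was not separated. Genes within 10 Mb of *Akr1d1* did not differ more often than others: 9 of 80 (11.2%, exact 95% interval 5.28 to 20.3) had an unadjusted p under 0.05, against 11.96% elsewhere (Fisher's exact p = 1, two-sided). An allele that leaves a transcript, and *Akr1d1* RNA from the Hepa 1-6 tumour cells, stay open as untested.

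Female-biased genes were higher and male-biased genes lower in the libraries labelled KO. The 4 Y-linked genes gave no sign of female animals in that group, with a lowest value there of 0.822, while *Uty* in WT replicate 1 was at 0.280. They cannot decide the question, because RNA from the tumour cells was not separated. A ratio to the gene's own mean also does not show how much Y-linked RNA a library holds. A lower share of hepatocytes is argued against for the female-biased genes, whose score was higher by 0.957 (SE 0.237) while hepatocyte identity was at -0.07. For the male-biased genes it cannot be told apart from a change of their own, because their score minus that of hepatocyte identity differed by -0.12 (SE 0.13). A shift of the sex-biased programme with genotype may remain as a hypothesis, untested here, since *Akr1d1* goes against the labels.

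Macrophage, matrix and ductular lists were higher in the libraries labelled KO, the ductular one with overlapping scores. A lower share of hepatocytes that raised all other liver cells alike would raise endothelial markers too. KO minus WT, the macrophage and matrix scores exceeded the endothelial one by 0.38 (SE 0.14) and 0.34 (SE 0.08) with no overlap. The stellate cell score was higher by 0.11 (SE 0.04) with no overlap, so a lower share that raises only some cell types is not excluded. For the ductular list the difference from the endothelial score was 0.51 (SE 0.26) with overlap, so a lower share of hepatocytes cannot be told apart from a change of its own. KO replicate 1 as the sole source is argued against for these 3 lists by their medians without it, 0.21, 0.27 and 0.43, against 0.28, 0.25 and 0.50 with all libraries. They also passed camera without it (largest adjusted p 0.000928). That call carries little weight alone, as camera at its preset correlation called 3 to 19 lists in splits that mix the groups. Both interferon lists missed the threshold without KO replicate 1 (smaller camera adjusted p 0.121). A lost call cannot show that it was their sole source, as their medians stayed positive at 0.11 and 0.10. Kupffer cell markers did not pass (camera adjusted p = 0.0571); more infiltrating macrophages, or more tumour tissue in the pieces taken, stay open as untested.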
